A study of Gallus gallus with 8 samples.

How the data were processed

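Messenger RNA of chick embryo tissue was sequenced in 8 libraries, 1 per group, on an Illumina HiSeq instrument. The groups were the central and the anterior pre-streak epiblast, area opaca epiblast after 5 hours in contact with a grafted node and its ungrafted counterpart at HH4, and the neural plate, the anterior and the posterior preplacodal region and non-neural ectoderm at HH6/7. Per the labels, the pre-streak, area opaca and neural plate libraries came from 1 laboratory and the other 3 from another.

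The deposited count table holds raw counts per gene for 17329 genes, of which 16701 carry Ensembl identifiers and 628 RefSeq accessions. The deposited FPKM table holds fragments per kilobase scaled to the mapped fragments of the library, computed by the authors, for 17327 genes. The submitters' processing notes name TopHat2 and the chicken genome build galGal4, without versions of the software; the counting program, the annotation, the strand setting and the filters are not given in the sources used here. Columns were assigned to samples by the tissue codes in the count table's column names, and columns of the FPKM table by the library codes both tables share. The count column of the non-neural ectoderm has a prefix p in its tissue code that the label lacks. All main values come from the counts, and FPKM served as an alternative unit.

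FPKM columns were checked against the counts, separately for both kinds of identifier, by the correlation across genes of values centred on each gene's mean. Among Ensembl genes, 8 of 8 FPKM columns followed the counts of their own library best (r from 0.904 to 0.975). Among RefSeq genes, 0 of 7 did (r with the own library from -0.617 to 0.634), and the FPKM column of the non-neural ectoderm was empty for all 628. The column of the grafted area opaca, for example, followed the ungrafted counts there (r 0.926, 238 genes). FPKM values of RefSeq genes therefore stand under the wrong library, and no new assignment was attempted. Of the genes with at least 500 counts in all, 148 pairs with separate identifiers had the same counts in every library within 5% or 3 counts. Many of them were an Ensembl gene and a RefSeq gene, whose count columns thus go together. The pairs were found by this likeness, so RefSeq genes outside them were not checked in this way. Such repeats were kept in the counts of genes. Besides this, between 5 and 22 genes per library with at least 1000 counts are listed at 0 FPKM.

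Counts were scaled to library size (CPM) with TMM factors over the 8 libraries from edgeR 4.0.16 in R 4.3.3; DESeq2 1.42.0 gave the size factors of an alternative. Neither tool's test was used. Library totals ran from 13053810 to 138666339, so that 3 counts, the floor used for a count of 0, correspond to between 0.0205 and 0.238 CPM. The 95% interval of a CPM ratio is the exact Clopper-Pearson interval of a binomial conditional on the summed counts. With 1 library per group no test between groups was made. A gene is called higher or lower where the ratio reaches 2 and the higher library has at least 5 CPM. Further calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

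The 6 comparisons, the size rule, the gene lists and the rule for naming genes were set before the data were examined. Per comparison the rule names the 10 genes highest and the 10 lowest by the interval bound nearest to 1, among genes with at least 10 CPM in the higher library and a symbol that is not a placeholder (3365 genes have a placeholder), and members of the lists. There are 23 lists with 352 genes, of which 313 were matched, 11 of them through a synonym of the reference table. The others had no match by name and enter no list count, although the table holds some under another name (DUSP6 as MKP3, PRDM1 as BLIMP-1, DKK1 as DKK-1 and HNRNPK as HNRPK). Some genes that the rule names are not reported here. A member is measured where either library reaches 1 CPM. Members under 1 CPM in both libraries enter no count or median. A gene absent from 1 library is measured only through its level in the other. Medians are compared with 10000 random lists of the same size and given as a percentile of these. The random lists are drawn from measured genes in the same of 20 expression bins. A gene may belong to several lists. Tissue sets hold genes at least 2 times higher in 1 HH6/7 library than in each of the other 3, or in both preplacodal libraries than in the others, or in both pre-streak libraries than in all HH6/7 libraries. Correlations of ratios run across genes with at least 5 CPM in a library of each pair.

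Alternatives set beforehand were total counts without TMM, DESeq2 size factors, minimums of 1 CPM, of 20 CPM (correlations alone) or of 3 counts, a ratio of 4, an interval bound reaching 2, and FPKM with pseudocounts of 1 and 0.1. Alternatives chosen after seeing the data left out RefSeq genes (from counts and from FPKM), thinned all libraries to the smallest total, added these 4 genes to their lists, or formed the tissue sets without the non-neural ectoderm. The size rule was tested on simulated data: with counting noise alone, 100 of 100 genes with a 4-fold and 100 of 100 with a 3-fold difference were recovered in each comparison and 0 unchanged genes were called. With an assumed coefficient of variation of 0.2 in each library, between 160 and 221 unchanged genes were called, and with 0.4 between 2183 and 2423. These assumed values were not estimated from the data.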

Results

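The series profiled messenger RNA of chick embryo ectoderm by RNA sequencing in 8 libraries, 1 per group. At pre-streak stages the central and the anterior epiblast were sampled. At HH4 (Hamburger and Hamilton stage 4), Hensen's node, the organiser at the tip of the primitive streak, was grafted into the area opaca, extraembryonic ectoderm that does not normally form nervous system. After 5 hours the epiblast touching the graft was collected, and the area opaca of the opposite side of the same embryos served as the ungrafted control. At HH6/7 the neural plate, the anterior and the posterior preplacodal region (the precursors of cranial sense organs and ganglia) and head ectoderm that is neither neural nor placodal were dissected. The title of the series names the question: what tissue responding to the node and tissue forming placodes have in common at first, set against the border of the neural plate.

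Total counts were 100147917 in the central and 99718534 in the anterior pre-streak epiblast, 13053810 in the node-grafted and 14573663 in the ungrafted area opaca, 109869453 in the neural plate, 96256421 in the anterior and 138666339 in the posterior preplacodal region, and 58731944 in the non-neural ectoderm. Between 8980 and 9640 genes reached 5 CPM (counts scaled to the library total) in a library. Because each group has 1 library, no difference below has a replicate check; the intervals in brackets are exact 95% intervals of the CPM ratio and cover counting error only. Genes are called higher or lower by a rule of size, a ratio of at least 2 with at least 5 CPM in the higher library.

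Contact with the node for 5 hours went with a broad difference between the sides of the area opaca. Of 9494 genes at 5 CPM or more, 702 were higher and 833 lower on the grafted side. The axonal adhesion molecule CNTN2 (ENSGALG00000000653) stood at 165 CPM on the grafted and 0.0719 CPM on the ungrafted side, a ratio of 2296 [412, 90730.0] that rests on 1 ungrafted count. ETV4 (ENSGALG00000001188), an ETS factor switched on by FGF signalling, stood at 51.8 against 0.0719 CPM, a ratio of 719.8 [129, 28470.0] that also rests on 1 count. In the other direction the surface ectoderm regulator GRHL3 (ENSGALG00000004249) was 67.6-fold lower [50.7, 92.2], at 3.73 against 252 CPM, and the T-box gene TBX3 was 311-fold lower [85.7, 2571].

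Genes with the highest grafted-side ratios also included MKP3, an ERK phosphatase induced by FGF (118 against 0.719 CPM, 164-fold [88.8, 342]), GGT5 (100.1-fold [45.7, 274]) and the endothelin receptor EDNRB (379 against 5.18 CPM, 73.2-fold [58.0, 93.7]). The neurotrophin receptor NGFR, the microtubule regulator STMN2, the retinoic acid hydroxylase CYP26C1 and the T-box gene TBX6 had no count on the ungrafted side and were at least 97.4-fold, 89.3-fold, 58.4-fold and 57.0-fold higher on the grafted side, set against a floor of 3 counts. Genes with the lowest ratios also included WNT11 (87.8-fold lower [63.6, 125], at 2.93 against 258 CPM), WNT7B (0.0793 against 13.2 CPM), the anion transporter SLC26A9 (63.7-fold lower [44.2, 95.4]), the signalling regulator ARHGAP22 (54.5-fold lower [33.9, 93.9]), the epithelial ETS gene ELF5 (85.6-fold lower [29.0, 418]), the caudal gene CDXB (51.7-fold lower [26.0, 120.5]; its counts equal those listed under CDX4) and the secreted guidance factor SEMA3C (38.4-fold lower [20.7, 80.6]). The protease inhibitor SERPINB2 had no count on the grafted side and was at least 71.4-fold lower. With a minimum of 1 CPM in place of 5, 1151 genes were higher and 1318 lower.

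Among gene lists fixed before the data were examined, those of FGF feedback and of the neural plate had medians above those of random lists on the grafted side, and those of BMP signalling, the neural plate border and non-neural ectoderm below them; in the neural plate list most measured members passed no rule. Targets and inhibitors of FGF signalling had 12 measured members, 10 higher, 0 lower and 2 neither (median log2 ratio 2.73, percentile 100). DUSP6 of this list was not matched by name and is missing from these counts; it is listed in the table as MKP3, given above, and with it 11 of 13 were higher. Besides ETV4, DUSP5 (4.86 log2), DUSP4 (3.75), IL17RD (3.39, 165 against 15.8 CPM) and SPRY2 (3.21) led this list. Genes of the BMP pathway had 13 measured members, 0 higher, 9 lower and 4 neither (median log2 ratio -2.39, percentile 0). GATA2 stood at 21.7 against 357 CPM, MSX1 at 12.8 against 138, ID2 at 36.8 against 166 and BAMBI at 19.6 against 95.9 CPM. For MSX1, a gene listed by RefSeq accession, the deposited FPKM values gave a log2 ratio of 3.94, but the FPKM columns of such genes follow the counts of other libraries. The ligand BMP4 itself passed no rule, at a log2 ratio of -0.29.

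The early response to node signals had 11 measured members, 5 higher, 0 lower and 6 neither (median log2 ratio 1.46, percentile 100). OTX2 was 35.2-fold higher [26.1, 48.7], MYCN 6.29-fold [5.36, 7.41], SOX3 2.75-fold [2.50, 3.03] and the metalloprotease ASTL 3.05-fold [2.90, 3.20]. FPKM gave -2.49 log2 for SOX3, which is also listed by RefSeq accession. The neural plate list had 11 measured members of 27 matched, 4 higher, 1 lower and 6 neither (median log2 ratio 3.20, percentile 100). The others were under 1 CPM on both sides, and members without an ungrafted count were measured only through their grafted level. The RNA-binding protein MSI1 was 16.7-fold higher [13.8, 20.5] and LHX5, with no ungrafted count, at least 50.7-fold higher, while the Notch ligand DLL1 was 8.06-fold lower [4.94, 14.0]. SOX2, the general marker of neural plate, stood at 4.04 CPM with no ungrafted count, under the minimum of the rule, against 57.9 CPM in the HH6/7 neural plate. The early epiblast list had 14 measured members, 7 higher, 1 lower and 6 neither (median log2 ratio 0.74, percentile 100). PRDM14 (2.67), LIN28B (2.20) and DNMT3B (1.38) were higher, NANOG was lower (439.6 against 1094 CPM) and POUV, the chick POU5F3 gene, differed little (1314 against 1332 CPM).

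The neural plate border list had 12 measured members, 0 higher, 7 lower and 5 neither (median log2 ratio -1.86, percentile 0). PRDM1 of this list, which the table holds as BLIMP-1, was not matched by name and is missing from these counts; it was higher on the grafted side (41.9 against 3.24 CPM), and with it 1 of 13 was higher and 7 were lower. MSX2 (-3.94), DLX5 (-3.92) and TFAP2A (-2.01, 23.5 against 94.6 CPM) were lower. The non-neural ectoderm list had 22 measured members, 1 higher, 14 lower and 7 neither (median log2 ratio -1.67, percentile 0). The keratins KRT14 (-3.42), KRT19 (-1.61) and KRT18 (-1.36) and the ligand BMP7 (-2.16) were lower, TFAP2C was higher (1.02), and EPCAM (0.41) and CDH1 (-0.51) were neither. Preplacodal genes had 10 measured members, 2 higher, 2 lower and 6 neither (median log2 ratio -0.20, percentile 33.6). EYA2 (2.15) and HOMER2 (2.53) were higher and DLX3 lower (0.0793 against 8.63 CPM). The anterior placode list had 5 measured members of 15 matched, 2 higher, 2 lower and 1 neither (median log2 ratio 1.63, percentile 99). The posterior placode list had 6 measured members of 9 matched, 2 higher, 0 lower and 4 neither (median log2 ratio 2.49, percentile 99.9). Here MEIS2 (4.71) was higher.

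Genes of the node and axial mesoderm had 8 measured members of 14 matched, 3 higher, 0 lower and 5 neither (median log2 ratio 2.40, percentile 99.97). T (ENSGALG00000011489) stood at 25.7 against 0.216 CPM, CHRD at 8.32 CPM with no ungrafted count and GNOT1 at 27.1 against 5.03 CPM, while SHH had no count on either side and NOG 1 count on the grafted and 3 on the ungrafted side. The mesoderm list had 5 measured members of 18 matched, 2 higher, 1 lower and 2 neither (median log2 ratio -0.62, percentile 15.1). EOMES was 6.70-fold higher [6.05, 7.43] and HAND1 7.89-fold lower [4.43, 15.3]. Genes of endoderm, hypoblast and yolk had 14 measured members, 0 higher, 5 lower and 9 neither (median log2 ratio -2.55, percentile 0). TTR (0.238 against 7.91 CPM), GATA4 (0.317 against 8.99) and RBP4 (5.63 against 33.1) were lower. Caudal and Hox genes had 4 measured members of 14 matched, 0 higher, 2 lower and 2 neither (median log2 ratio -3.78, percentile 0.02). Blood and endothelial markers had 5 measured members of 15 matched, 0 higher, 0 lower and 5 neither (median log2 ratio 1.24, percentile 89.6). Neural crest genes had 4 measured members of 11 matched, 0 higher, 0 lower and 4 neither (median log2 ratio -0.46, percentile 16.6).

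The WNT list had 11 measured members, 2 higher, 4 lower and 5 neither (median log2 ratio -0.54, percentile 1.06). AXIN2 was 6.57-fold lower [5.78, 7.49] and the secreted inhibitor SFRP1 16.9-fold higher [14.8, 19.4]. The Notch list had 10 measured members, 3 higher, 2 lower and 5 neither (median log2 ratio 0.19, percentile 75.4). JAG1 (3.42) and LFNG (3.61) were higher and JAG2 (-2.54) lower. The retinoic acid list had 10 measured members, 2 higher, 2 lower and 6 neither (median log2 ratio -0.23, percentile 26.2). The degrading enzyme CYP26A1 was 44.1-fold higher [14.7, 217] and the receptor RARB 5.22-fold lower [4.01, 6.89]. The cell cycle list had 20 measured members, 1 higher, 0 lower and 19 neither (median log2 ratio 0.14, percentile 94.8). The gene past the rule was CCND1 (151 against 30.0 CPM). The stress list had 18 measured members, 2 higher, 2 lower and 14 neither (median log2 ratio -0.04, percentile 37.9). The glycolysis and hypoxia list had 22 measured members, 2 higher, 2 lower and 18 neither (median log2 ratio -0.12, percentile 8.37). Housekeeping genes had 16 measured members, 0 higher, 0 lower and 16 neither (median log2 ratio -0.02, percentile 41.6).

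**Figure D1:**
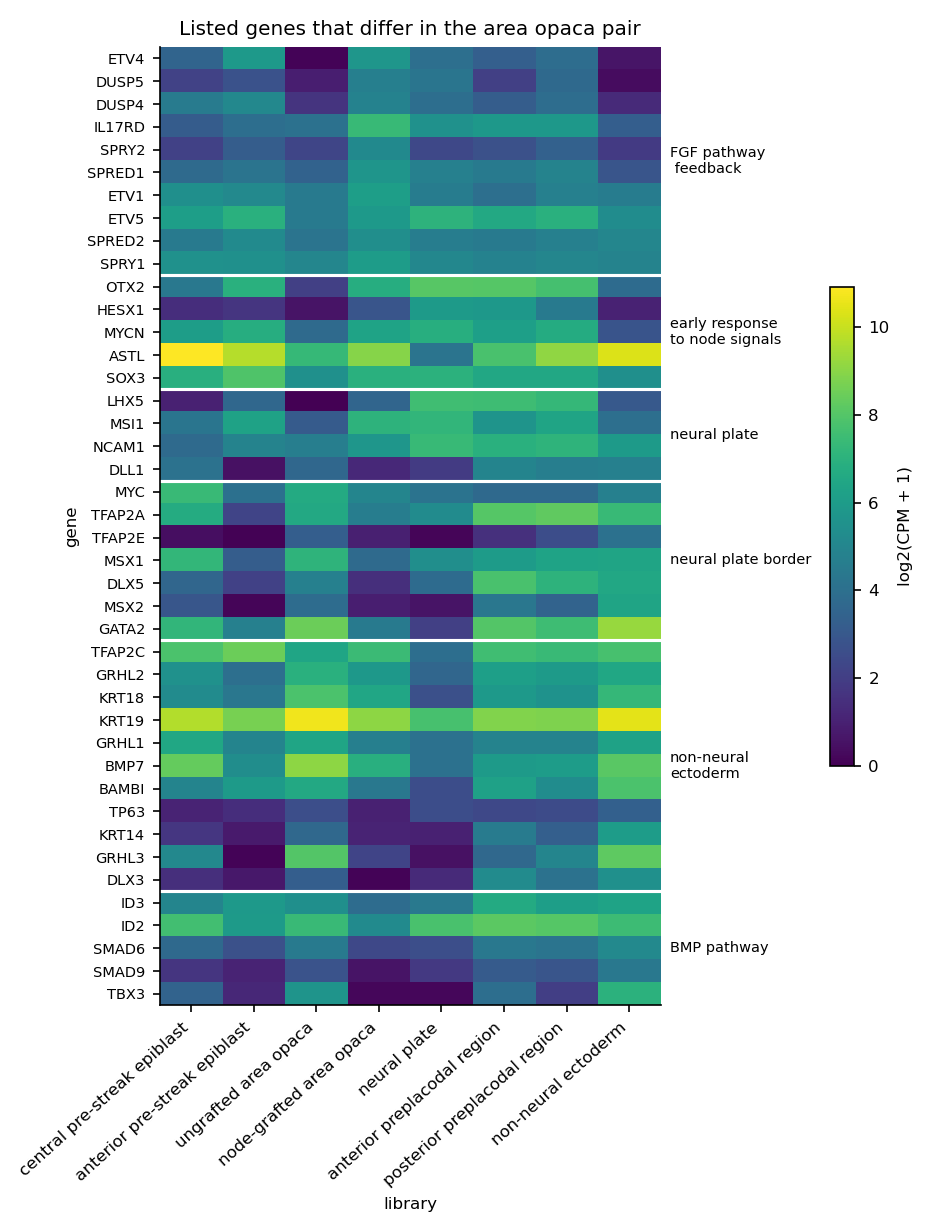
Expression of the listed genes that met the size rule in the area opaca pair, as log2(CPM + 1), in the 8 libraries (columns), grouped by the list in which each first appears. ETV4 is dark in the ungrafted area opaca (0.0719 CPM) and bright in the node-grafted one (51.8 CPM), and GRHL3 shows the opposite (252 and 3.73 CPM).

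Profiles of the other tissues were then looked up in the area opaca pair, with which they share no library. Genes highest in the neural plate among the 4 HH6/7 tissues numbered 162, of which 121 were measured in the pair; 46 were higher and 3 lower on the grafted side, with a median log2 ratio of 1.31 (percentile 100 of 10000 random sets matched on expression) that was smaller with FPKM and a pseudocount of 1, at 0.75. Of the 59 genes higher in both preplacodal libraries than in neural plate and non-neural ectoderm, 55 were measured, 29 were higher, none was lower, and the median was 1.65 (percentile 100). Genes highest in the non-neural ectoderm went the other way: of 584 measured, 10 were higher and 391 lower, with a median of -1.65 (percentile 0; -1.41 with FPKM and a pseudocount of 1). Of the 24 genes highest in the anterior preplacodal region 14 were measured, 2 were higher and 2 lower, and the median was 0.78 (percentile 99.85; 0.49 with DESeq2 size factors). All 7 genes highest in the posterior one were measured; the 2 higher ones were CXCL14 and JSC, which have like counts and so stand for 1 gene, and none was lower. The median of this set was 0.27 (percentile 86.3; 0.48 with DESeq2 size factors and 0.49 with FPKM and a pseudocount of 1) and is the value of a ribosomal RNA gene. Of the 111 genes higher in both pre-streak libraries than in every HH6/7 library 105 were measured, 35 were higher and 6 lower, with a median of 0.31 (percentile 99.99). When the preplacodal sets were formed without the non-neural ectoderm library, a choice made after seeing the data, genes shared by preplacodal and non-neural ectoderm entered them, and the medians turned to -0.73 for both preplacodal libraries (398 genes) and -1.53 for the anterior one (60 genes).

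**Figure D2:**
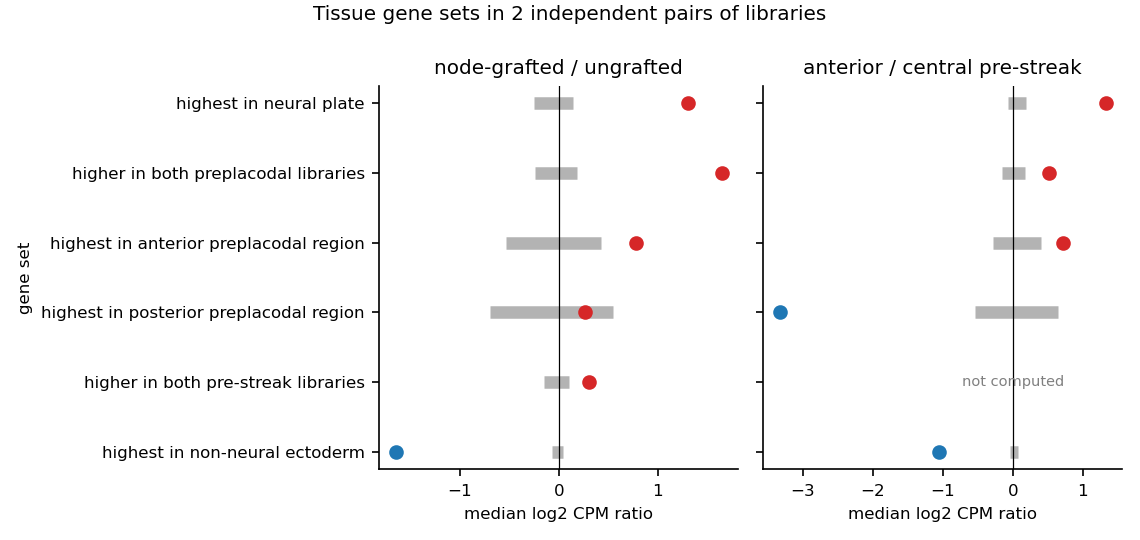
Median log2 CPM ratio of each tissue gene set (points; red above and blue below 0) in the area opaca pair (left) and in the pre-streak pair (right), with the central 95% range of 10000 random sets matched on expression (grey bars). In the area opaca pair the neural plate set lies at 1.31 and the non-neural ectoderm set at -1.65, both outside the grey range; the pre-streak set was not looked up in the pre-streak pair, which defines it.

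Across genes, the grafted over ungrafted ratio went with the neural plate over non-neural ratio (Pearson r 0.678, Spearman coefficient 0.580, 9261 genes at 5 CPM in a library of each pair; genes are not independent replicates). Of these genes 324 were higher in both pairs and 575 lower in both, where lists independent of each other would share 45.4 and 87.4, and 43 and 10 went in opposite directions. With the anterior over central pre-streak ratio r was 0.658 (Spearman 0.512), and 250 genes were higher and 300 lower in both, against 29.1 and 29.4 for independent lists. The ratios of the anterior and the posterior preplacodal region over non-neural ectoderm gave r of 0.727 and 0.740; these 2 and the neural plate ratio share the non-neural ectoderm library, and differences among the 4 correlations were not tested. As whole profiles, the grafted library ranked nearer than the ungrafted one to the neural plate (Spearman coefficient 0.895 against 0.819) and the anterior pre-streak epiblast (0.918 against 0.838). The same held for both preplacodal regions (0.918 against 0.871 and 0.924 against 0.869) and, by less, for the central pre-streak epiblast (0.927 against 0.912). The ungrafted library ranked nearer to the non-neural ectoderm (0.946 against 0.902). Outside its pair, the grafted library lay nearest to the central pre-streak epiblast. Of the HH6/7 libraries it lay furthest from the neural plate.

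**Figure D3:**
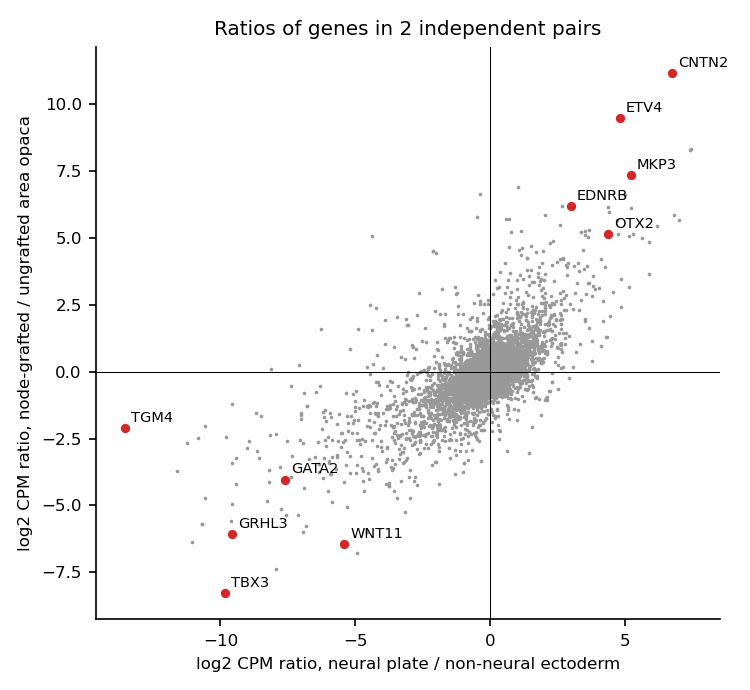
Log2 CPM ratio of node-grafted over ungrafted area opaca (vertical axis) against that of neural plate over non-neural ectoderm (horizontal axis), 1 point per gene for 9261 genes, named genes in red. The points run from TBX3 and GRHL3, low in both pairs, to CNTN2, high in both (r 0.678).

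Within the pre-streak epiblast, the lists of node and axial mesoderm and of the neural plate had higher medians in the anterior region. Those of the neural plate border, BMP signalling and non-neural ectoderm, which share members, had higher medians in the central region. Of 9453 genes, 562 were higher and 469 lower anteriorly. The BMP family member ADMP (ENSGALG00000028044) was 61.0-fold higher [52.5, 71.3], at 115 against 1.88 CPM, and the BMP antagonist CHRD 22.7-fold higher [20.4, 25.3]. In the central region GRHL3 was 438-fold higher [212, 1091], at 32.8 against 0.0749 CPM, CDX2 50.9-fold [36.3, 73.7] and WNT3A 53.5-fold [34.5, 87.9].

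The anterior epiblast also had more of the secreted kinase PKDCC (55.7-fold [46.3, 67.5]), KIAA1045 (34.8-fold), CYP26C1 (31.4-fold) and CYP26A1 (30.2-fold), the innate immune receptor TLR4 (26.2-fold), carbonic anhydrase CA2 (198 against 9.17 CPM) and CNTN2 (20.8-fold [18.2, 24.0]). The central epiblast had more of CALD1 (37.2-fold), DLL1 (16.3 against 0.407 CPM), the transglutaminase TGM4 (32.0-fold), TFAP2A (104 against 3.73 CPM), SPTLC3 (32.2-fold), WNT5A (27.8-fold) and the nucleoside transporter SLC28A3 (277 against 11.3 CPM). Node and axial mesoderm genes had 8 measured members, 4 higher, 1 lower and 3 neither (median log2 ratio 1.62, percentile 100). DKK1 of this list, which the table holds as DKK-1, is missing from these counts; with it 4 were higher and 2 lower, and the median was 0.72 (percentile 99.6). The neural plate border list had 9 measured members, 0 higher, 7 lower and 2 neither (median log2 ratio -2.79, percentile 0). PRDM1 is again missing from these counts (BLIMP-1, 52.2 against 14.6 CPM). MSX1 (1.94 log2 with FPKM) stood at 8.47 CPM anteriorly against 149 centrally and MYC at 15.5 against 169. The non-neural ectoderm list had 22 measured members, 1 higher, 10 lower and 11 neither (median log2 ratio -1.28, percentile 0). BMP7 (-3.01) and BMP4 (-2.79) were lower. The BMP list had 12 measured members, 1 higher, 7 lower and 4 neither (median log2 ratio -1.41, percentile 0). FGF feedback genes had 10 measured members, 2 higher, 0 lower and 8 neither (median log2 ratio 0.75, percentile 99.97). ETV4 was 5.46-fold higher [5.09, 5.85]. The neural plate list had 13 measured members, 5 higher, 1 lower and 7 neither (median log2 ratio 1.17, percentile 99.9). LHX5 (3.50), MSI1 (2.08) and FABP7 (1.67) were higher. The anterior placode list had 6 measured members, 1 higher, 0 lower and 5 neither (median log2 ratio -0.20, percentile 20.1). OTX2 was 6.04-fold higher [5.75, 6.35], while NANOG (-0.18) and POUV (0.18) were neither. The neural plate set defined above had a median log2 ratio of 1.33 (percentile 100) and the non-neural ectoderm set of -1.06 (percentile 0) in this pair.

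At HH6/7 the neural plate and the non-neural ectoderm differed in 1010 genes higher and 1223 lower in the neural plate, of 10130 at 5 CPM or more. The forebrain gene FEZF2 (ENSGALG00000007184) stood at 40.7 CPM against no count, at least 861-fold higher, SOX2 (ENSGALG00000008848) at 57.9 against 0.142 CPM (409-fold [215, 895]) and ZIC2 at 119 against 0.157 CPM (758-fold [412, 1582]). GRHL3 (761-fold lower [566, 1047]), TBX3 (910.5-fold lower [560.3, 1594]) and UPK1B, a protein of epithelial surface plaques (0.255 against 385 CPM), were among the lowest. The neural plate library came from another laboratory than the non-neural ectoderm, so laboratory as well as tissue differs in this pair; mitochondrially encoded genes took 3.16% of its counts against 5.88%, and 5.31% and 4.97% in the anterior and posterior preplacodal libraries of the second laboratory.

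Further genes highest in the neural plate by ratio were the midbrain homeobox gene DMBX1 (36.3 CPM against 1 count), ZIC1 (at least 489-fold), FMN2 (23.3 against 0.0315 CPM), RFX4 (13.1 against 0.0157 CPM), the fatty acid ligase ACSL6 (127-fold [100.1, 162]) and CYP26C1 (249 against 2.20 CPM). On the non-neural side were TGM4 (105 CPM against 1 count), the TEAD cofactor VGLL1 (at least 1843-fold lower in the neural plate), CDXB (at least 1650.0-fold), WNT9B (at least 915-fold), VEPH1 (42.3 against 0.0176 CPM), the glucose transporter SLC5A1 (762-fold [634, 923]) and FIBIN (1142 against 1.67 CPM). The neural plate list had 17 measured members, 11 higher, 2 lower and 4 neither (median log2 ratio 3.85, percentile 100). NKX-6.2 (5.98), HESX1 (5.87) and LHX5 (4.68, 187 against 7.32 CPM) were higher and DLL1 lower (-3.25). The non-neural ectoderm list had 24 measured members, 0 higher, 19 lower and 5 neither (median log2 ratio -2.76, percentile 0). KRT18 stood at 5.27 against 153 CPM and BAMBI at 4.94 against 225. The BMP list had 13 measured members, 0 higher, 10 lower and 3 neither (median log2 ratio -2.75, percentile 0). FGF feedback genes had 10 measured members, 6 higher, 0 lower and 4 neither (median log2 ratio 1.91, percentile 99.99). The neural plate border list had 15 measured members, 3 higher, 7 lower and 5 neither (median log2 ratio -0.99, percentile 0.03). PAX-7 (7.56) and ZIC1 were higher, GATA2 (-7.60) and MSX2 (-7.40) lower.

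In the same pair the Notch list had 9 measured members, 4 higher, 2 lower and 3 neither (median log2 ratio 2.02, percentile 100). NRARP (3.36) and LFNG (2.82) were higher and JAG2 (-4.40) lower. The retinoic acid hydroxylases CYP26A1 (6.16) and CYP26C1 were higher in the neural plate and the synthetic enzyme ALDH1A2 (-3.54) lower. The non-neural ectoderm library also held transcripts of other kinds. Blood and endothelial markers had 10 measured members, 0 higher, 4 lower and 6 neither (median log2 ratio -4.11, percentile 0.01). KDR stood at 30.3 CPM there against 1.59 in the neural plate, 1.26 in the anterior and 2.37 in the posterior preplacodal region, LMO2 at 17.5 against 2.75, 1.10 and 1.67, and CDH5 at 7.68 against 0.0791, 0.0194 and 0.308 CPM. Endoderm and yolk genes had 15 measured members, 0 higher, 8 lower and 7 neither (median log2 ratio -3.18, percentile 0). TTR stood at 31.7 CPM in non-neural ectoderm against 0.800 in neural plate. Caudal and Hox genes had 9 measured members, 0 higher, 5 lower and 4 neither (median log2 ratio -6.35, percentile 0).

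The anterior preplacodal region, compared with non-neural ectoderm of the same stage and laboratory, had 689 genes higher and 704 lower of 10058. As whole profiles, the anterior and the posterior preplacodal library lay nearer to the neural plate (Spearman coefficient 0.954 and 0.965) than to non-neural ectoderm (0.930 and 0.921). DMBX1 stood at 43.7 CPM against 1 count in non-neural ectoderm, FEZF2 was at least 265-fold higher, and SOX2 103-fold higher [54.0, 225]. ZIC2 (134-fold [72.8, 280.1]), CYP26C1 (72.1-fold), CYP26A1 (56.5-fold), HESX1 (53.0-fold [41.6, 68.4]), ACSL6 (44.5-fold), CNTN2 (31.7-fold) and NGFR (16.4 against 0.409 CPM) followed. Lowest were CDXB (115-fold lower [83.8, 162]), KLHL31 (42.7-fold), TGM4 (37.7-fold), TTR (37.5-fold), RERG (31.8-fold), SPTLC3 (27.9-fold), GRHL3 (24.5-fold [23.2, 26.0]), CALD1 (25.6-fold), VGLL1 (23.1-fold) and the endothelial receptor KDR (24.0-fold). The preplacodal list had 11 measured members, 6 higher, 0 lower and 5 neither (median log2 ratio 1.25, percentile 100). EYA2 (73.4 against 12.5 CPM) and IRX1 (39.3 against 7.44) were higher. The anterior placode list had 10 measured members, 7 higher, 0 lower and 3 neither (median log2 ratio 3.83, percentile 100). SS5R, the somatostatin receptor SSTR5 (5.49), PITX1 (4.48) and PAX-6 (3.11) were higher. The neural plate border list had 15 measured members, 4 higher, 4 lower and 7 neither (median log2 ratio 0.66, percentile 99.9). DLX6 (3.79) and DLX5 (1.25) were higher, MSX2 (-2.11) and GATA2 (-1.26) lower. The non-neural ectoderm list had 24 measured members, 2 higher, 11 lower and 11 neither (median log2 ratio -0.39, percentile 0). Blood and endothelial markers had 10 measured members, 0 higher, 4 lower and 6 neither (median log2 ratio -3.94, percentile 0).

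The posterior preplacodal region had 737 genes higher and 810 lower than non-neural ectoderm of 10054. PAX-7, a paired box gene of the border and neural crest, stood at 37.4 against 0.126 CPM (297-fold [150.5, 688]), ZIC2 was 327-fold higher [178, 683] and SOX2 100.1-fold higher [52.6, 219]. DMBX1 (44.0 CPM against 1 count), CYP26C1 (77.3-fold), ACSL6 (68.5-fold), CYP26A1 (60.0-fold), BRINP2 (54.4-fold) and CNTN2 (46.3-fold) were also among the highest. At the other end stood TTR (101-fold lower [75.3, 138]), FIBIN (67.4-fold), TGM4 (51.2-fold), CDXB (54.9-fold), WNT9B (57.8-fold), TBX3 (41.9-fold), KLHL31 (39.0-fold), HAND1 (33.7-fold), WISP1 (29.8-fold) and RERG (29.1-fold). The preplacodal list had 12 measured members, 3 higher, 1 lower and 8 neither (median log2 ratio 0.87, percentile 99.9). EYA2 stood at 74.3 against 12.5 CPM. The posterior placode list had 8 measured members, 5 higher, 1 lower and 2 neither (median log2 ratio 2.03, percentile 99.99). GBX2 (5.23), SOX8 (3.45) and IRX2 (3.41) were higher. Neural crest genes had 10 measured members, 3 higher, 1 lower and 6 neither (median log2 ratio 0.38, percentile 87.5). TFAP2B (5.43) was higher and ETS1 (-1.29) lower. FGF feedback genes had 10 measured members, 7 higher, 0 lower and 3 neither (median log2 ratio 2.0, percentile 100). The non-neural ectoderm list had 24 measured members, 1 higher, 11 lower and 12 neither (median log2 ratio -0.73, percentile 0). Blood and endothelial markers had 10 measured members, 0 higher, 4 lower and 6 neither (median log2 ratio -3.60, percentile 0).

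The 2 preplacodal regions were the most alike of all pairs of libraries (Spearman coefficient 0.992 across 10626 genes), and 71 genes were higher and 77 lower anteriorly of 9778. Together these are fewer than the 161 simulated unchanged genes that the rule called in this pair. That simulation assumed a coefficient of variation of 0.2 in each library, a value not estimated from the data. In the data 94.5% of the genes of this pair differed by less than 0.5 log2. The simulation therefore does not say whether these calls are noise. Of them 56 higher and 59 lower genes had an interval bound over 2. Higher anteriorly were FEZF2 (6.45-fold [5.66, 7.36]), HAND1 (6.10-fold [5.40, 6.90]), the neuropeptide gene SST (33.7 against 5.90 CPM, 5.71-fold [5.30, 6.16]), FIBIN (5.46-fold), TBX3 (4.71-fold), ARHGEF4 (4.66-fold), TNR (4.41-fold), PAX-6 (35.5 against 9.74 CPM, 3.65-fold [3.43, 3.88]) and EYA1 (3.56-fold [3.33, 3.81]). Higher posteriorly were the chemokine CXCL14 (20.5-fold [16.5, 25.9]), the hindbrain-boundary gene GBX2 (14.8 against 1.06 CPM, 14.0-fold [11.5, 17.1]), PAX-7 (9.11-fold [8.25, 10.1]), the WNT target SP5 (6.08-fold [5.62, 6.58]), ZEB2 (5.93-fold), CCNA1 (5.15-fold), the GABA-synthesising enzyme GAD67 (4.59-fold), DUSP5 (3.94-fold) and ENC1 (3.76-fold). CXCL14, listed by RefSeq accession and with like counts under the name JSC, had a log2 ratio of 1.97 with FPKM.

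In this pair the anterior placode list had 9 measured members, 4 higher, 0 lower and 5 neither (median log2 ratio 1.28, percentile 100). HESX1 stood at 55.8 against 21.7 CPM. The posterior placode list had 8 measured members, 0 higher, 4 lower and 4 neither (median log2 ratio -1.12, percentile 0). Caudal and Hox genes had 5 measured members, 0 higher, 1 lower and 4 neither (median log2 ratio -2.63, percentile 0). Neural crest genes had 10 measured members, 1 higher, 3 lower and 6 neither (median log2 ratio -0.67, percentile 0). DCT (1.81) was higher, CDH6 (-1.55) and TFAP2B (-2.36) lower. The WNT list had 11 measured members, 0 higher, 2 lower and 9 neither (median log2 ratio -0.32, percentile 0). AXIN2 was lower (-1.30). The preplacodal list had 12 measured members, 3 higher, 0 lower and 9 neither (median log2 ratio 0.11, percentile 97.5). EYA2 (-0.02) and SIX4 (0.04) were neither. The mesoderm list had 9 measured members, 3 higher, 1 lower and 5 neither (median log2 ratio -0.13, percentile 4.47). NKX2-5 (1.24) and ISL1 (1.02) were higher anteriorly.

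**Figure D4:**
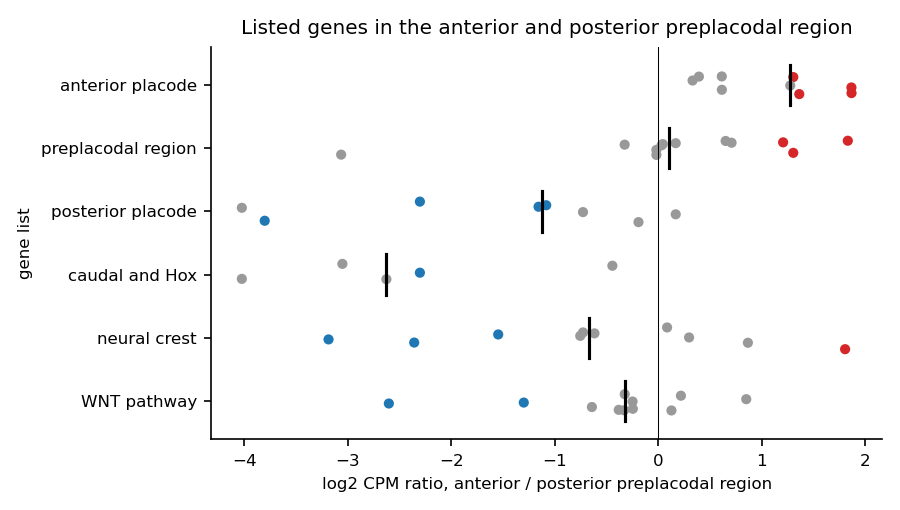
Log2 CPM ratio of the anterior over the posterior preplacodal region for the measured members of 6 gene lists (points, 1 per gene; red higher and blue lower by the size rule, grey neither; black bars mark list medians, vertical scatter is for legibility). The anterior placode list has its median at 1.28 and the posterior placode list at -1.12.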

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

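All tests in this part were chosen after the results they weigh were seen. No gene was higher in 1 preplacodal region and lower in the other against non-neural ectoderm, and groups of 1 library allow no check for a library that stands apart from its group.

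The node-grafted area opaca has lower levels of surface ectoderm, BMP and caudal genes and higher levels of a few genes of the node. Node cells carried over with the epiblast would dilute its transcripts and bring those of the node; 37 genes with at least 10 CPM on the ungrafted side had a grafted over ungrafted interval wholly under 0.1, which by dilution would take a library made mostly of such cells. Among all listed node genes PTCH1 (32.4 CPM), GNOT1 (27.1 CPM), T (25.7 CPM) and CHRD (8.32 CPM) were highest on the grafted side and SHH had no count. PTCH1 passed no rule between the 2 sides, while GNOT1, T and CHRD were higher on the grafted side. No library of the node gives the levels to expect. Carried-over cells therefore cannot be told apart from a response of the epiblast as the source of the lower genes. The same holds for the node genes themselves, with 37.5% of the measured list higher and a median log2 ratio of 2.40. Hypoblast or yolk cells in the ungrafted library cannot be told apart from a response either, since 35.7% of 14 measured genes of that list (5 genes) were lower on the grafted side and none was higher, with a median of -2.55; a response to the graft stays open and untested.

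The non-neural ectoderm library differs from the other HH6/7 libraries in blood and endothelial, yolk, caudal and Hox genes. Cells of another type in the non-neural ectoderm library are a candidate explanation for the blood and endothelial genes: 9 of 10 measured members were highest in it, led by KDR (30.3 CPM), LMO2 (17.5 CPM), FLT1 (7.98 CPM) and CDH5 (7.68 CPM). Blood or endothelial cells are argued against as the source of the whole set of genes highest there, since 61.5% of it also stood at least 2 times above the other 3 HH6/7 libraries in the ungrafted area opaca, where the median of the blood list was 0.252 CPM; yolk or endoderm cells were not tested and stay open for the set, since TTR stood at 7.91 CPM in that library. Ectoderm from behind the head in the non-neural ectoderm library cannot be told apart from other sources: 7 of 10 measured caudal and Hox genes were highest in it, among them CDX4 (43.5 CPM), but CDX4 stood at 32.8 CPM in the ungrafted area opaca too, and the labels do not say whether the prefix p in the name of this library's count column stands for a posterior position. A difference between tissues stays open and untested.

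The neural plate was compared with non-neural ectoderm from another laboratory. A difference between laboratories is argued against as the source of the genes that were also higher on the grafted side, a pair of libraries from 1 laboratory: 324 genes were higher in both comparisons, where 45.4 would be for independent lists. The same holds for the 575 genes lower in both, against 87.4 for independent lists; the other genes lower in the neural plate were not tested. Of the other 686 genes higher in the neural plate, 50% (343 genes) were also higher in a preplacodal region than in non-neural ectoderm within the other laboratory. For these 343 a difference from non-neural ectoderm appears without a change of laboratory, although both comparisons share the non-neural ectoderm library. For the rest of the 686, laboratory and tissue cannot be told apart. A difference between tissues stays open and untested.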

How the results depend on the processing

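Alternatives that leave out RefSeq genes, thin the libraries, add unmatched genes to lists or leave out the non-neural ectoderm library were chosen after the results were seen; the others were not. Of 294 comparisons of a main count, set, set median, correlation or similarity with an alternative, 209 stayed within the margin set for them.

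No paired analysis was possible because each side of the area opaca gave 1 library. DESeq2 size factors, the interval bound, thinning and leaving out RefSeq genes from the counts moved none of these values past its margin, but the margins are wide. They were a fixed factor for counts of genes and followed the range of random sets for set medians. With the interval bound, genes higher and lower on the grafted side were 505 and 610, against 702 and 833. The median of the anterior preplacodal set on the grafted side was 0.49 with DESeq2 size factors, against 0.78. No scaling shifted the median of all genes by 0.1 log2 or more. Without TMM the median of the non-neural ectoderm set was -1.60. Changes with the minimum or the ratio follow from their construction, since they admit more or fewer genes.

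With a minimum of 1 CPM, genes higher and lower numbered 1151 and 1318 on the grafted side, 969 and 726 in the anterior epiblast, and 151 and 126 in the anterior over the posterior preplacodal region; 1060 were higher in the anterior preplacodal region than in non-neural ectoderm. The sets of neural plate, anterior and posterior preplacodal region held 251, 38 and 13 genes. Correlations of the grafted ratio with the anterior epiblast, neural plate, anterior and posterior preplacodal ratios were 0.577, 0.602, 0.641 and 0.658. With 20 CPM they were 0.681 (anterior epiblast), 0.749 and 0.765 (preplacodal). With no minimum beyond 3 counts, genes higher and lower were 1411 and 1602 (grafted), 1634 and 1309 (anterior epiblast), 1869 and 2701 (neural plate), 1631 and 1749 (anterior preplacodal), 1645 and 1972 (posterior preplacodal) and 644 and 511 (anterior over posterior). The sets then held 365 (neural plate), 123 (anterior), 56 (posterior preplacodal), 1366 (non-neural), 317 (pre-streak) and 160 genes (both preplacodal). With a ratio of at least 4, genes higher and lower were 285 and 319, 142 and 161, 364 and 579, 194 and 238, 210 and 288, and 13 and 14 in the same order. The sets held 28, 1, 2, 203, 47 and 10 genes.

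With FPKM and a pseudocount of 1, 437 genes were higher in the anterior and 460 in the posterior preplacodal region than in non-neural ectoderm, with RefSeq genes or without them, and 368 in the anterior epiblast without them. The posterior preplacodal set held 17 genes (19 with a pseudocount of 0.1). Set medians were 0.75 and 1.07 (neural plate) and -1.41 and -1.54 (non-neural) with pseudocounts of 1 and 0.1, and 2.06 with 0.1 for both preplacodal libraries. Correlations were 0.559 with the anterior epiblast (0.612 without RefSeq genes), 0.686 with the anterior and 0.684 with the posterior preplacodal ratio. The median of the mesoderm list in the posterior preplacodal region against non-neural ectoderm was 0.84 from counts and reversed to -0.097 and -0.067 with FPKM. The cause was not tested for these.

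Values of single genes and lists also depended on the unit. With FPKM and a pseudocount of 1, of the log2 ratios of named genes, counted once per comparison, 182 moved outside their counting interval, 5 reversed and 36 stayed within it; of list medians 44 moved past their margin, 1 reversed and 93 stayed. With a pseudocount of 0.1 these numbers were 80, 5 and 138, and 21, 1 and 116. Without RefSeq genes and with a pseudocount of 1 they were 181, 0 and 36, and 42, 1 and 95. Total counts moved 2 of these ratios, DESeq2 size factors 4, and both moved 0 list medians.

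Single genes reversed with FPKM alone, all of them RefSeq genes, whose FPKM columns follow the counts of other libraries. With pseudocounts of 1 and 0.1, the log2 ratio of grafted over ungrafted was 3.94 and 3.96 for MSX1, -2.49 and -2.49 for SOX3 and -4.34 and -4.34 for ENS-1. MSX1 stood at 1.94 and 1.95 in the anterior over central epiblast, and CXCL14 at 1.97 and 2.02 in the anterior over posterior preplacodal region. Without RefSeq genes 0 named genes reversed.

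Without the non-neural ectoderm library, sets of 60 (anterior), 22 (posterior) and 398 genes (both preplacodal) had medians of -1.53, -0.50 and -0.73 on the grafted side; the first and the last reversed. By construction these sets take in genes shared with non-neural ectoderm. The higher level of the set of both preplacodal libraries on the grafted side thus holds only for genes set apart from that tissue. Of the anterior set so set apart, 2 of 14 measured genes were higher and 2 lower (median at percentile 99.85). The median of the posterior set lay within random sets (percentile 86.3), as did that of the preplacodal list (percentile 33.6).

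Adding the genes found under another name to their lists (MKP3, BLIMP-1, DKK-1 and HNRPK) left 27 of 30 list medians within their margin and reversed 0. The median of the node and axial mesoderm list was 0.72 in the anterior over central epiblast, and those of the neural plate border and FGF lists -0.13 and -0.52 in the anterior over posterior preplacodal region.

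Depth limits the area opaca pair most: a gene without a count in the ungrafted library is bounded at 0.216 CPM.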

Other observations

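Genes in this part were chosen after their values were seen, and no test was run on them. NANOG stood at 1213 CPM in the central and 1068 CPM in the anterior pre-streak epiblast, at 1094 CPM in the ungrafted area opaca and at 34.1 CPM in the neural plate. EOMES stood at 220 and 156 CPM in the pre-streak libraries, at 31.2 CPM in the ungrafted and 209 CPM in the grafted area opaca, and at 8.95 CPM or less in the HH6/7 libraries. BLIMP-1, a transcriptional repressor, stood at 3.24 CPM in the ungrafted and 41.9 CPM in the grafted area opaca and at 164 and 167 CPM in the anterior and posterior preplacodal regions.

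ENS-1, a gene of a repeated family whose reads may map to several copies, had 3389 CPM on the grafted and 148 CPM on the ungrafted side, but its log2 ratio was -4.34 with FPKM, whose columns follow other libraries for this gene. CXCL14 stood at 92.5 CPM in the central and 9.18 CPM in the anterior pre-streak epiblast, and at 89.2 CPM on the grafted and 31.9 CPM on the ungrafted side.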
